A study of Mus musculus with 15 samples.

How the data were processed

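The deposited table holds counts per gene symbol, 24420 symbols by 15 columns, and per the labels and the submitters' processing notes these are read counts assigned to genes. The notes name CASAVA 1.8, HISAT2 2.0.1, featureCounts, Subread, R 3.3.3, DESeq2 1.14.1 and genome build mm10. The gene annotation, the strand setting and the handling of reads with several positions are not given in the sources used here. All values were whole numbers and column totals ran from 38.3 M to 99.4 M (M, mega), which fits counts and no scaled unit. Reads were not aligned or counted again. RNA came from cerebellum, and the columns name the group but no replicate number, so libraries are called by group and column order (WT-5 is the column in place 5 of the WT columns) and no column was matched to a single sample entry.

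Depth in mega counts was 81.7, 71.2, 83.0, 73.9 and 38.3 in WT-1 to WT-5, 70.6, 84.3, 96.5, 84.5 and 70.8 in 82Q-1 to 82Q-5, and 99.4, 73.2, 96.4, 72.0 and 95.7 in 82Q_M120A-1 to 82Q_M120A-5. A gene at 1 CPM has 38 counts in the shallowest library and 99 in the deepest, which gives a counting error (Poisson coefficient of variation) of 16.2% and 10%. Replicate libraries differ by more than counting error, with a chi-square per degree of freedom of 6.96 to 71.55 over 30 pairs within groups. The common biological coefficient of variation was 0.105. PC1 of the log2 CPM values held 36.6% of the variance, PC2 14.2% and PC3 11.6%, and on PC1 WT lay at -31.9 to -16.8, 82Q at -13.5 to 2.5 and 82Q_M120A at 22.4 to 40.4.

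The main test was an edgeR quasi-likelihood fit of all 15 libraries with group as the only factor (edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, glmQLFit with robust estimation, TMM factors, filterByExpr with its defaults), two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold for a call. Genes were tested if the filter kept them, which left 16808 genes with 99.99% of the counts; 7612 were not tested, 3300 of them without a count in any library. The fit had 12 residual degrees of freedom and a median prior of 5.3. Strain and age are fixed by group and cannot enter the fit. Standard errors are approximate: the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Coordinates are from GENCODE M21 (16132 tested genes) and RefSeq on GRCm38.p6 (641), both the mm10 assembly, and 35 tested genes have none.

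Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists with at least 3 tested members, and beside it with the correlation estimated per list, with fry, and with an exact two-sided permutation test of the list score per library (252 arrangements of 5 against 5, smallest p = 0.00794). The score is the mean log2 CPM of the tested members with a prior count of 2. Members were also adjusted over the list alone. The 31 lists, written before the data were examined from general knowledge of cerebellar cell types and pathways, are Purkinje cell, mGluR1 and calcium signalling, early ATXN1 82Q repressed genes, neuronal ion channels, PKA and cAMP signalling, ATXN1 complex, CIC target genes, cholecystokinin, GABA and glycine synapse, glutamate receptors and postsynaptic density, granule cell, molecular layer interneuron and Golgi cell, astrocyte and Bergmann glia, reactive glia, oligodendrocyte, oligodendrocyte precursor, microglia, vascular, meninges and fibroblast, choroid plexus, blood, brainstem and cerebellar nuclei, immediate early genes, circadian clock, cholesterol synthesis, cytosolic heat shock, unfolded protein response, mitochondrially encoded, nuclear oxidative phosphorylation, strain-variable transcripts and sex-linked transcripts. Of these 28 could be tested. None of the 13 mitochondrially encoded genes is in the table, of the 5 blood genes only 1 was tested, and of the cholecystokinin list only 2, Cck among them. 15 genes are in more than 1 list.

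Genes are named by a rule fixed before the data were examined: Atxn1 and Prkaca everywhere; per comparison the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and no overlap between the groups, leaving out predicted models; per list up to 4 called members with the smallest adjusted p, or the 2 most abundant members where none was called; and 8 genes with the largest 82Q change that were called back toward WT. The text prints fewer of these, and any other gene is said to be chosen after its values were seen. Without overlap were 16.6% of tested genes in 82Q against WT, 25.3% in 82Q_M120A against WT and 12.1% in 82Q_M120A against 82Q, against 0.79% by chance. A gene moved back if it was called in 82Q against WT and in the opposite direction in 82Q_M120A against 82Q.

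Alternatives written before the data were examined were DESeq2 1.42.0, limma-voom, RLE factors, library size only, no low-count filter, a mean of at least 1 CPM, a fit of only the groups compared, adjusted p under 0.01, a test against a 1.2-fold change, leaving out the sex-linked and strain-variable genes, and leaving out each library. The choroid plexus score and the Xist level per library, alone and together, were added as covariates later. DESeq2 called 3515, 6403 and 3646 genes in 82Q against WT, 82Q_M120A against WT and 82Q_M120A against 82Q, and 3101, 5998 and 3132 of these were called by edgeR as well. The calls were set beside regroupings of the 10 libraries of a comparison. Shared calls were set beside 20 simulations of unchanged groups, independent lists and 20 splits of the shared libraries.

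The pipeline was tested on simulated data with the depth, abundance and spread of these libraries and 50 genes changed at each of 1.2-, 1.5-, 2- and 3-fold. It called 48%, 66%, 94% and 100% of them in 82Q against WT, 40%, 72%, 94% and 96% in 82Q_M120A against WT, and 34%, 70%, 90% and 98% in 82Q_M120A against 82Q. Among the calls 9 of 163, 7 of 158 and 7 of 153 were genes left unchanged. In this setting changes of 1.2-fold were missed more often than found. Only 200 genes were changed, while the real comparisons had 3142, 6118 and 3175 calls. With more changed genes the adjusted p threshold admits larger p-values, so these shares do not carry over to the real data.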

Results

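Cerebellar RNA was compared between 3 mouse groups of 5 libraries each: wild type (WT), mice with an Atxn1[82Q] allele (82Q), and mice that also carry CalphaLoxM120A, an altered form of the protein kinase A catalytic subunit that Prkaca encodes (82Q_M120A). Expanded Atxn1 causes spinocerebellar ataxia type 1, in which Purkinje cells, the output neurons of the cerebellar cortex, are the main site of disease. WT and 82Q are both labelled FVB/nJ and 9 weeks old, and 82Q_M120A is labelled a mix of C57BL/6J and FVB/nJ and 8 weeks old. Each comparison with 82Q_M120A therefore joins the kinase allele with strain and age, and no group carries the kinase allele alone. The labels call the 5 samples of a group replicates and do not say more about their origin, so the p-values measure the spread between these samples. Values are TMM-scaled CPM (counts scaled to a common library size), mean ± SD with n = 5 per group. Log2 fold changes are given with an approximate standard error derived from the test statistic. Adjusted p values come from edgeR quasi-likelihood tests with Benjamini-Hochberg correction over 16808 genes.

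Counts of the mouse genes Atxn1 and Prkaca differed little. Atxn1 (chr13:45549755-45965008, mm10) stood at 52.9 ± 6.2 CPM in WT, 56.5 ± 1.75 in 82Q and 53.9 ± 2.14 in 82Q_M120A and was not called in any comparison (adjusted p = 0.308 for 82Q against WT, 0.764 for 82Q_M120A against WT and 0.467 for 82Q_M120A against 82Q, edgeR quasi-likelihood). Leaving out WT-4 moved the first of these to a log2 fold change of 0.16 with adjusted p = 0.0269. Gene counts do not separate alleles, and whether reads of the expanded allele count to mouse Atxn1 at all is not settled by the sources used here, so these values need not measure it. Prkaca (chr8:83972993-83996443) stood at 168 ± 3.6 CPM in WT and 164 ± 5.76 in 82Q, not called (adjusted p = 0.557), and fell to 145 ± 5.54 in 82Q_M120A. That is a log2 fold change of -0.21 ± 0.03 against WT (1.15-fold lower, adjusted p = 5.09e-05, edgeR quasi-likelihood) and of -0.18 ± 0.03 against 82Q (1.13-fold, adjusted p = 0.000633).

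**Figure D1:**
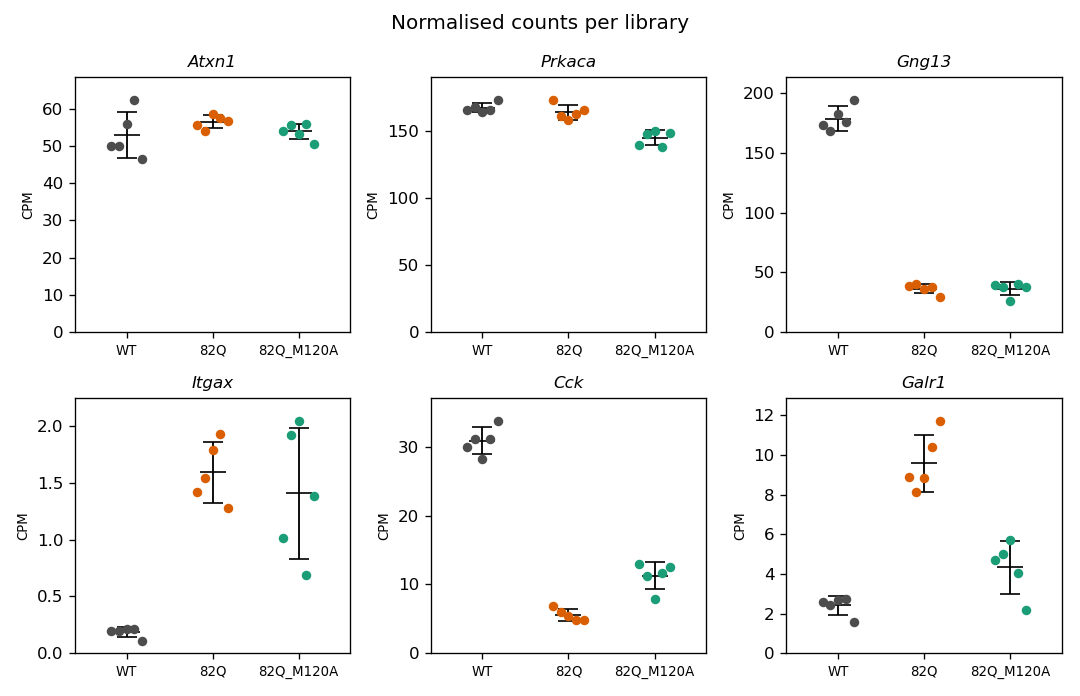
Normalised counts (CPM, vertical axes) of Atxn1, Prkaca, Gng13, Itgax, Cck and Galr1 in the 5 libraries of WT, 82Q and 82Q_M120A; points are libraries, bars are mean and SD. Cck, for example, has means of 30.9, 5.58 and 11.3 CPM.

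In 82Q against WT the Purkinje cell program was lower and genes of microglia and reactive glia were higher. Gng13 (chr17:25717171-25719406), a G protein gamma subunit of Purkinje cells, fell from 179 ± 10.1 to 36.6 ± 4.09 CPM (4.89-fold, adjusted p = 6.04e-10, edgeR quasi-likelihood with Benjamini-Hochberg correction). The largest changes are given for called genes with a mean of at least 1 CPM and no overlap between the groups, predicted models left out. Downward these were Trabd2b (chr4:114406724-114615098), a membrane protease that acts on Wnt proteins, from 35.2 ± 1.85 to 4.08 ± 0.726 CPM (log2 fold change -3.11 ± 0.19), and Gchfr (chr2:119167773-119172390), a regulator of tetrahydrobiopterin synthesis, from 14 ± 0.661 to 1.65 ± 0.0774 CPM (-3.08 ± 0.14). Col5a1, a fibrillar collagen chain, fell by 2.74 log2 units, the growth factor gene Bmp8a by 2.50 and the tetraspanin gene Tspan11 by 2.47. The neuropeptide gene Cck (chr9:121489824-121495694) fell by 2.47 and the growth factor gene Fgf7 (chr2:126034658-126091185) by 2.45. Under the same limits the largest rise was that of Itgax (chr7:128129547-128150657), which marks activated microglia, from 0.185 ± 0.044 to 1.59 ± 0.265 CPM (log2 fold change 3.04 ± 0.29, adjusted p = 3.72e-07). It rests on 663 counts in 82Q and 66 in WT, a ratio of 8.31 with a 95% counting interval of 6.44 to 10.9 that leaves out the variation between samples. Mslnl followed under these limits (2.28 ± 0.17), then the galanin receptor gene Galr1 (chr18:82392380-82406777), from 2.41 ± 0.466 to 9.6 ± 1.45 CPM (1.97 ± 0.21, adjusted p = 5.86e-06), and Hrk, a BH3-only promoter of apoptosis, from 10.9 ± 0.593 to 34.4 ± 4.22 CPM (1.66 ± 0.14). Lipoprotein lipase gene Lpl rose by 1.56, Cnksr1 by 1.53 and Slc4a1 by 1.44. Complement gene C4b (1.43 ± 0.09) and the astrocyte filament gene Gfap (chr11:102887336-102900912), from 157 ± 15.3 to 424 ± 18.2 CPM (1.43 ± 0.12), were also among the 10 largest rises that meet them.

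Of all tested genes, 3142 (18.7%) were called in 82Q against WT, 1451 higher and 1691 lower. The median absolute log2 fold change of the called genes was 0.26, and 236 changed more than 2-fold, 88 higher and 148 lower. The share of higher genes among the calls was 46.2%, against 73% with library size as the only scaling and 32.8% in a test against a 1.2-fold change, so the balance of directions depends on the scaling. Fgf7 shares its stretch of chromosome 2 with Fam227b, and the strand setting of the counting is not given in the sources used here. Reads of overlapping genes therefore cannot be told apart. Fam227b did not fall with Fgf7 in 82Q (4.67 to 5.51 CPM in WT, 5.03 to 6.65 in 82Q). This argues against reads of Fam227b as the source of the Fgf7 fall in 82Q against WT.

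Among the gene lists fixed before the data were examined, 10 of 28 were called in 82Q against WT by camera with a preset correlation of 0.01, 3 upward and 7 downward. Of the 24 Purkinje cell genes 23 fell and 1 was not called (23 fell when adjusted over the list alone), with a median log2 fold change of -1.08 (camera adjusted p = 5.94e-122, and 0.000115 with an estimated correlation). Icmt, a methyltransferase gene known to be repressed early by expanded Atxn1, fell from 796 ± 41.4 to 275 ± 13.5 CPM (-1.53 ± 0.06) and the inositol trisphosphate kinase gene Itpka by 1.65 log2 units. The score of this list, the mean log2 CPM of its members, was 6.79 ± 0.09 in 82Q and 7.91 ± 0.05 in WT (two-sided exact permutation test, p = 0.00794, the smallest possible value with 5 against 5; adjusted p = 0.0247). All 20 genes of mGluR1 and calcium signalling fell, and all 20 when adjusted over the list alone (median -1.05, camera adjusted p = 9.82e-101, estimated 0.000115). The diacylglycerol lipase gene Dagla went from 157 ± 4.2 to 57 ± 3.32 CPM, and the inositol trisphosphate receptor gene Itpr1 from 5020 ± 232 to 1990 ± 175. The 6 genes known as early targets of Atxn1[82Q] all fell (6 when adjusted over the list alone, median -1.23, estimated 0.000115). All 6 belong to the Purkinje cell or mGluR1 lists as well, and these 3 lists hold 36 different genes.

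Synaptic and channel genes followed in part. Of 23 neuronal ion channel genes 10 fell, 4 rose and 9 were not called (12 fell and 4 rose when adjusted over the list alone, camera adjusted p = 6.98e-11, estimated 0.0055), led by the T-type calcium channel gene Cacna1g, from 449 ± 11.9 to 175 ± 17.6 CPM. Of 22 genes of glutamate receptors and the postsynaptic density 12 fell and 10 were not called (13 fell when adjusted over the list alone, camera adjusted p = 8.5e-10, estimated 0.000487), among them the scaffold gene Shank2, from 285 to 148 CPM (-0.94 ± 0.05). Cholesterol synthesis genes fell in 14 of 18 cases (15 when adjusted over the list alone, camera adjusted p = 6.33e-06, but adjusted p = 0.399 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 8 of 32 cases, with Ndufa1 lower by a log2 fold change of -0.22 ± 0.05 (12 when adjusted over the list alone, camera adjusted p = 0.00203, but adjusted p = 0.738 with an estimated correlation).

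Microglia and reactive glia rose most clearly among the glial lists. All 16 microglia genes were higher, also when adjusted over the list alone (median 0.74, camera adjusted p = 1.77e-28, estimated 0.00201). Csf1r, the receptor microglia need to survive, rose from 27.8 ± 1.81 to 44.7 ± 1.73 CPM (0.69 ± 0.05) and complement gene C1qb from 8.62 ± 0.658 to 15.5 ± 1.15. Of 16 reactive glia genes 13 rose and 3 were not called (14 rose when adjusted over the list alone, median 0.71, camera adjusted p = 1.73e-12, estimated 0.00153). Oligodendrocyte genes rose in 10 of 16 cases (13 when adjusted over the list alone, camera adjusted p = 1.55e-06, but adjusted p = 0.399 with an estimated correlation), with myelin gene Mbp going from 2610 ± 227 to 3270 ± 328 CPM. Astrocyte and Bergmann glia genes were divided, with 5 higher, 3 lower and 7 not called (7 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.23). Water channel gene Aqp4 rose from 360 to 506 CPM.

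Camera did not call the lists of the kinase pathway, of the Atxn1 protein complex or of CIC targets in 82Q against WT. Fry, which asks whether the list itself changed, called all 3 (adjusted p = 0.0482, 0.0396 and 0.0269). Of 25 genes of PKA and cAMP signalling 4 rose and 2 fell (camera adjusted p = 0.437), with phosphodiesterase gene Pde4b higher by 0.19 ± 0.04. In the ATXN1 complex list 1 of 14 genes rose and 2 fell (adjusted p = 0.536), Rora, a nuclear receptor Purkinje cells depend on, from 453 to 328 CPM. The transcriptional repressor CIC binds Atxn1, and of 12 CIC target genes 4 fell and 1 rose (5 fell and 1 rose when adjusted over the list alone, camera adjusted p = 0.196). Their list score was 5.24 ± 0.13 against 5.46 ± 0.1 (two-sided exact permutation test, p = 0.0159, adjusted p = 0.0404). Cyclin gene Ccnd1 was the one that rose, from 27.1 ± 2.2 to 39.5 ± 1.52 CPM, and Etv4 fell by 0.60 log2 units. GABA and glycine synapse genes were divided (3 higher, 3 lower, 10 not called, adjusted p = 0.72), with the GABA synthesis gene Gad1 falling from 756 to 641 CPM. Few members were called among granule cell genes (1 higher and 2 lower of 16, adjusted p = 0.72), genes of molecular layer interneurons and Golgi cells (2 higher of 12, 0.447), oligodendrocyte precursors (2 higher of 8, 0.338) and vascular genes (3 higher of 16, 0.26).

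**Figure D2:**
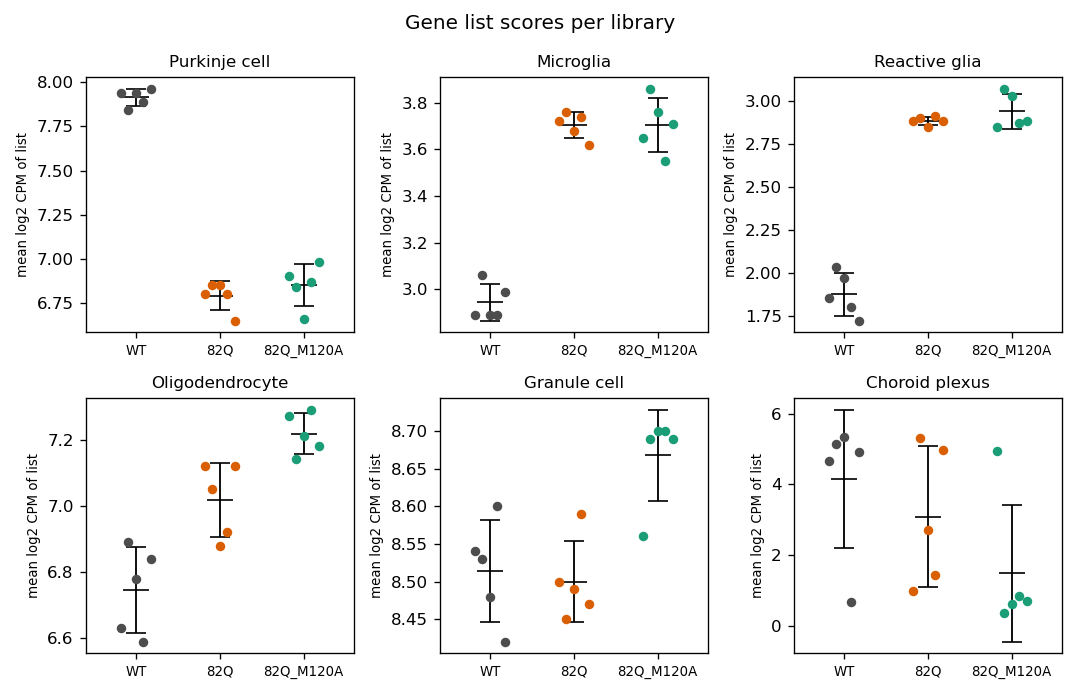
Scores of the Purkinje cell, microglia, reactive glia, oligodendrocyte, granule cell and choroid plexus lists, each the mean log2 CPM of the members (vertical axes), in WT, 82Q and 82Q_M120A; points are libraries, bars are mean and SD. The Purkinje cell score averages 7.91, 6.79 and 6.85.

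In 82Q_M120A against WT Purkinje cell genes were lower and most genes of microglia and reactive glia higher, as in 82Q, with further changes beside them. Gchfr fell from 14 ± 0.661 to 0.569 ± 0.203 CPM (log2 fold change -4.59 ± 0.15, adjusted p = 9.56e-13, edgeR quasi-likelihood with Benjamini-Hochberg correction). Col6a3 (chr1:90765923-90843971), a collagen VI chain, fell from 26.3 ± 12.8 to 2.15 ± 0.725 CPM, Fgf7 by 3.03 log2 units and Bmp8a by 2.81. Fam227b, which overlaps Fgf7, was lower here as well (4.67 to 5.51 CPM in WT, 0.694 to 1.02 in 82Q_M120A). Shared reads may therefore hold part of this Fgf7 fall. Upward the order under the same limits began with Fam205c, with 1419 counts against 7 (ratio 156, counting interval 75.6 to 389), and Strc, with 1979 against 39 (39.1, 28.5 to 55.1). Next came the mitotic checkpoint gene Bub1b (4.49 ± 0.94, adjusted p = 0.00231, but 0.079 by limma-voom), Rpl29 (4.32 ± 0.16), the lens filament gene Bfsp2 (3.86 ± 0.29) and Pttg1 (3.15 ± 0.20). Fcrls (chr3:87250758-87263738), an Fc receptor-like gene of microglia, followed, from 1.31 ± 0.376 to 10.9 ± 1.58 CPM (3.03 ± 0.16, adjusted p = 1.96e-10), and then Itgax, at 1.41 ± 0.578 (2.87 ± 0.29). In total 6118 genes were called (36.4%), 3129 higher and 2989 lower, and 630 changed more than 2-fold (348 higher, 282 lower). The higher share was 51.1%, against 68.8% with library size as the only scaling.

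Camera called 12 of the 28 lists in 82Q_M120A against WT, 5 upward and 7 downward. Purkinje cell genes fell in 23 of 24 cases (23 when adjusted over the list alone, median -1.04, camera adjusted p = 1.64e-70, estimated 0.00112), Icmt by 1.40 log2 units. Of the mGluR1 and calcium signalling genes 19 of 20 fell (median -0.93, estimated 0.00112) and of the early targets 6 of 6 (median -1.26, estimated 0.00112). Microglia genes rose in 14 of 16 cases and fell in 1 (15 and 1 when adjusted over the list alone, camera adjusted p = 7.79e-18, estimated 0.0125), with C1qb at 21.2 ± 1.5 CPM (1.3 ± 0.07). The one that fell was the microglia marker gene Tmem119, from 7.24 to 6.22 CPM (-0.22 ± 0.06, adjusted p = 0.00594). In 82Q it had risen to 8.7 CPM (0.26 ± 0.06, adjusted p = 0.00289). Reactive glia genes rose in 11 of 16 cases (median 0.85, estimated 0.00852), among them Cst7, a cathepsin inhibitor gene of activated microglia (4.11 ± 0.36, from 26 to 584 counts over 5 libraries, ratio 17.3 with a counting interval of 11.7 to 26.7). Ion channel genes (9 lower, 2 higher of 23, estimated 0.0309) and glutamate receptor and postsynaptic density genes (13 lower, 3 higher of 22, estimated 0.00852) kept their calls.

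The other 5 called lists lost the call with an estimated correlation. Oligodendrocyte genes rose in 14 of 16 cases, myelin gene Mobp from 224 to 376 CPM (0.74 ± 0.07; camera adjusted p = 7.91e-10, but adjusted p = 0.193 with an estimated correlation). Nuclear oxidative phosphorylation genes fell in 23 of 32 cases, Cox5a from 207 to 159 CPM (29 when adjusted over the list alone; camera adjusted p = 1.16e-06, but adjusted p = 0.543 with an estimated correlation). Vascular genes rose in 7 of 16 cases, led by the endothelial transporter gene Slco1a4, from 44.7 to 75 CPM (camera adjusted p = 0.007, but adjusted p = 0.314 with an estimated correlation). Granule cell genes rose in 9 of 16 cases, Fat2 by 0.52 (camera adjusted p = 0.021, but adjusted p = 0.722 with an estimated correlation); without WT-5 the list had adjusted p = 0.0506. Cholesterol synthesis genes fell in 7 of 18 cases and rose in 1 (camera adjusted p = 0.0393, but adjusted p = 0.837 with an estimated correlation). With the choroid plexus score of each library as a covariate the granule cell list (median 0.085, adjusted p = 0.237) and the cholesterol synthesis list (median -0.075, adjusted p = 0.291) were not called. The cholesterol synthesis call was also lost without WT-1 (adjusted p = 0.051), WT-2 (0.121), WT-3 (0.103), 82Q_M120A-2 (0.0944) or 82Q_M120A-5 (0.0844).

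In 82Q_M120A against 82Q most Purkinje cell genes kept their low level. Most of the largest differences lay in genes outside the fixed lists. The lists hold only a small part of the 16808 tested genes, so this does not show that they were spared. Car8, a Purkinje cell protein that binds the inositol trisphosphate receptor, rose from 554 ± 51.7 to 771 ± 105 CPM (log2 fold change 0.48 ± 0.08, adjusted p = 6e-04, edgeR quasi-likelihood with Benjamini-Hochberg correction) against 1430 ± 75.1 in WT. Rgs8 (chr1:153653025-153700323), a regulator of G protein signalling in Purkinje cells, rose from 410 ± 33.4 to 578 ± 131 (0.50 ± 0.13, adjusted p = 0.0143) against 1660 ± 102 in WT, and Skor2 rose by 0.31. These were the 3 of 24 Purkinje cell genes called, and the list score was 6.85 ± 0.12 against 6.79 ± 0.09 (exact permutation test, two-sided, p = 0.373; camera adjusted p = 0.546). Of the mGluR1 and calcium signalling genes 4 of 20 rose (5 when adjusted over the list alone, camera adjusted p = 0.0957), Dgkz by 0.31 ± 0.05 and Plcb3 by 0.32. None of the 6 early targets was called (camera adjusted p = 0.849), with Itpr1 at -0.11 (adjusted p = 0.397).

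Outside the lists, Col6a3 fell from 29.4 ± 7.16 to 2.15 ± 0.725 CPM (log2 fold change -3.78 ± 0.40, adjusted p = 2.8e-05, edgeR quasi-likelihood), Fam227b (chr2:125983483-126152004) by 2.82 log2 units and the thyrotropin-releasing hormone receptor gene Trhr by 2.58. Reads of Fam227b cannot be told apart from those of Fgf7, which it overlaps. The nucleotidase gene Nt5c1b fell by 2.42, with uneven libraries (0.0393 to 1.1 CPM in 82Q_M120A, 2.14 to 2.89 in 82Q). A630020A06 fell by 2.41. Pla2g4e (chr2:120166412-120245335), a phospholipase A2 gene, fell from 57.8 ± 4.6 to 11.2 ± 2.12 CPM (-2.37 ± 0.11, edgeR quasi-likelihood adjusted p = 1.28e-09). Upward, Fam205c (chr4:42868004-42874234) had 1419 counts over the 5 libraries against 13, a ratio of 102 (counting interval 59.2 to 191), and Strc (chr2:121363728-121387168), a gene of the inner ear, 1979 against 57, a ratio of 32.3 (24.8 to 42.8). Bfsp2 rose by 3.78 ± 0.28 and Pttg1 (chr11:43420250-43426251), which encodes securin, from 1.8 to 15.1 ± 5.17 CPM (3.07 ± 0.20, adjusted p = 4.06e-08). Rpl29, at 3.12 CPM in 82Q and 61.1 ± 14.9 in 82Q_M120A, and Dynlt1b, at 0.168 and 2.91 ± 1.8, have close copies elsewhere in the genome with which reads can be shared, so their rises are uncertain. Altogether 3175 genes were called (18.9%), 1724 higher and 1451 lower, and 334 changed more than 2-fold, 198 higher and 136 lower.

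**Figure D3:**
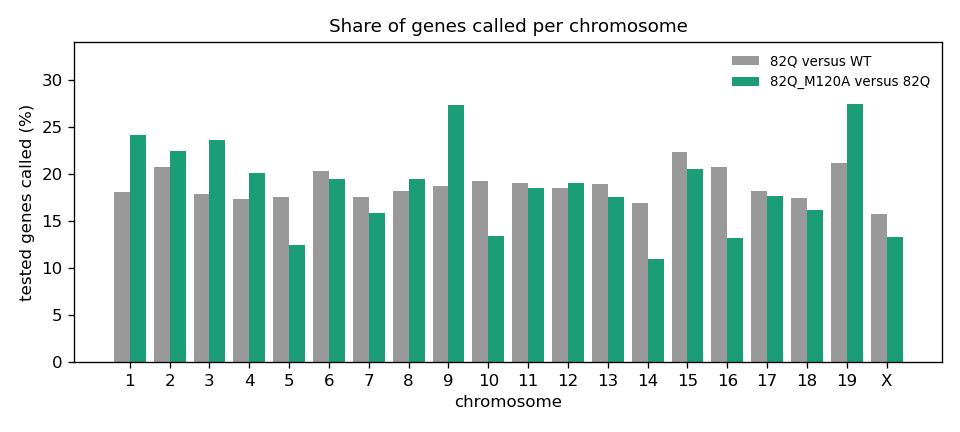
Share of tested genes called per chromosome (vertical axis, percent; horizontal axis, chromosome) in 82Q versus WT and in 82Q_M120A versus 82Q. The second ranges from 11% on chromosome 14 to 27.4% on chromosome 19.

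Camera called 3 lists in 82Q_M120A against 82Q and none with an estimated correlation (lowest adjusted p = 0.945). Of these, fry called the granule cell list (adjusted p = 0.0191) but not oligodendrocyte (0.0953) or nuclear oxidative phosphorylation genes (0.103). Granule cell genes rose in 8 of 16 cases, calretinin gene Calb2 from 254 to 344 CPM and Chn2 from 449 to 555 (12 when adjusted over the list alone; camera adjusted p = 0.000384, but adjusted p = 0.945 with an estimated correlation). The granule cell score was 8.67 ± 0.06 against 8.5 ± 0.05 (exact permutation test, two-sided, p = 0.0159, adjusted p = 0.111). Oligodendrocyte genes rose in 7 of 16 cases (7 when adjusted over the list alone; camera adjusted p = 0.00327, but adjusted p = 0.945 with an estimated correlation), with Mobp higher by 0.46 ± 0.07 and the transferrin gene Trf by 0.67 ± 0.11. Nuclear oxidative phosphorylation genes fell in 10 of 32 cases, Cox5a by 0.28 log2 units (11 when adjusted over the list alone; camera adjusted p = 0.00327, but adjusted p = 0.945 with an estimated correlation), and that call was lost without 82Q_M120A-4 (adjusted p = 0.0904). In lists camera did not call, microglia gene Tmem119 fell by 0.48 ± 0.06 while C1qb rose by 0.46 (3 higher and 2 lower of 16, camera adjusted p = 0.947). Slco1a4 led the vascular genes (0.70 ± 0.06; 4 higher of 16, adjusted p = 0.0562, and 0.0235 by fry). GABA synapse genes fell in 4 of 16 cases, Gad2 by 0.31 (camera adjusted p = 0.182, and 0.0235 by fry). In the PKA and cAMP list 5 of 25 genes rose and 4 fell (adjusted p = 0.72), and none of the 14 ATXN1 complex genes was called (adjusted p = 0.95).

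**Figure D4:**
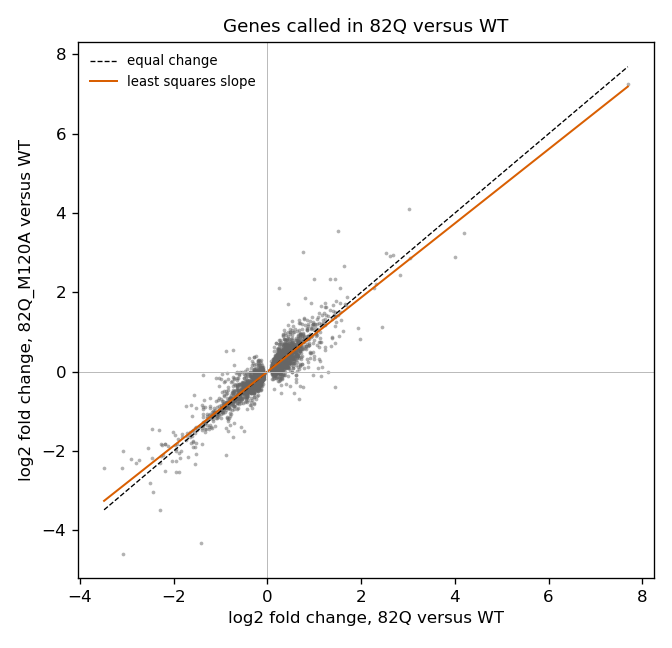
Log2 fold change of 82Q_M120A versus WT (vertical) against that of 82Q versus WT (horizontal) for the 3142 genes called in 82Q versus WT; the dashed line marks equal change and the solid line the least squares slope of 0.935.

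Cck and Galr1 were among the 34 genes with an 82Q change above 2-fold that were called toward the WT level in 82Q_M120A. Cck rose back from 5.58 ± 0.887 to 11.3 ± 1.97 CPM (2.02-fold, adjusted p = 2.66e-05, edgeR quasi-likelihood with Benjamini-Hochberg correction) against 30.9 ± 1.98 in WT, and Galr1 fell back from 9.6 ± 1.45 to 4.33 ± 1.35 (log2 fold change -1.15 ± 0.20, adjusted p = 0.00106) against 2.41 ± 0.466. Smaller returns were those of Trabd2b (0.68 ± 0.18), Col5a1 (0.52 ± 0.13) and the inflammasome gene Nlrp10 (0.83 ± 0.18), all still lower than in WT. Ccnd1 moved the other way, from 39.5 ± 1.52 to 60.5 ± 2.89 CPM (0.61 ± 0.05). Of the 3142 genes called in 82Q against WT, 435 (13.8%) were called toward the WT level and 300 further away from it. Among the 236 with changes above 2-fold 34 moved back and 12 further. Choosing genes for a large change on the shared 82Q libraries favours moves back, and no chance value was computed for these 34 and 12.

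Over these 3142 genes the slope of the 82Q_M120A change on the 82Q change was 0.935 (jackknife SE 0.058 over libraries, 0.90 to 0.957 with 1 library left out), where 1 is an equal change and 0 the WT level. Choosing genes and measuring the slope on the same libraries biases it, and with the libraries divided between these steps the median slope over 20 divisions was 0.969 (0.93 to 1.013). Called Purkinje cell genes had a slope of 0.925, mGluR1 and calcium signalling genes 0.886, microglia genes 1.055, reactive glia genes 1.158, oligodendrocyte genes 1.362 and cholesterol synthesis genes 0.713. These list slopes rest on 10 to 23 members called on the same libraries. No standard error or value with divided libraries was computed for them, so their differences from 1 and from each other were not tested.

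Shared libraries tie these counts together, so comparison values are given beside those over all called genes. For the 435 genes that moved back, independent lists of the same sizes would share 299 genes in opposite directions and 295 in the same. With the 82Q libraries split between the comparisons the median over 20 splits was 165.5 opposite (125 to 204) against 125 for independent lists, and 148.5 in the same direction (92 to 229) against 121.5. In 20 simulations without any change no gene was called in both. Groups without real change give little to call, so this sets no chance level for the counts of shared calls. The simulated correlation of the fold changes was -0.482, against -0.037 observed and 0.039 with the split. The covariance observed exceeded the simulated -0.0139 by 0.0093. Between the comparisons of 82Q and of 82Q_M120A with WT, 2331 genes were called in the same direction (1007 higher, 1324 lower) and 46 in opposite directions. Independent lists would share 571, and the WT split gave 1386.5 (1146 to 1465) against 247.5 for independent lists. The correlation was 0.598 against 0.513 simulated and 0.461 with the split, and the covariance exceeded the simulated 0.015 by 0.079.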

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

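The tests of gene position, of neighbouring genes within groups, of the Purkinje cell share, of the choroid plexus pattern and with covariates were chosen after the result was seen, and the regroupings before. The prediction for the region around Prkaca was written before that test. It starts from the lower Prkaca level, itself a result of these data. Genes called in 82Q_M120A against 82Q lie beside each other along the chromosomes: 901 pairs of neighbouring tested genes were both called, against a mean of 599.1 in 1000 shuffles within bins of expression (546 to 651), a ratio of 1.504. The share called within 5 Mb of Prkaca was 36% (40 of 111 genes) against 18.9% of all genes, 1.91 times as high (Fisher exact test, p = 2.4e-05), and the lower Prkaca level lies in that region. Both values are in line with alleles of the mixed strain changing genes near them, but calls also lay together in 82Q against WT, of 1 strain label (ratio 1.159, 682 pairs against at most 663), and in 82Q_M120A against WT (1.09, 2422 against at most 2335). The Fisher test takes neighbouring genes as independent, but calls lie together, so its p-value overstates the evidence. No other window of the genome was compared with the region around Prkaca. A mix that still varies between the 5 libraries would make neighbouring genes vary together within 82Q_M120A. Their mean correlation there (0.0947, random pairs subtracted) lay above WT (0.0543) and below 82Q (0.1188, difference -0.0241), which leaves such a mix open. What part of these calls belongs to the kinase allele with the region around it, to strain or to age stays open, since no group separates them.

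Tissue and sex were tested as other sources of the calls. With the choroid plexus score as a covariate 83.8% of the calls in 82Q_M120A against 82Q, 93.6% of those in 82Q against WT and 80.5% of those in 82Q_M120A against WT remained, and with the Xist level 90.4%, 84.8% and 95.1%. With both together 80.1%, 84.6% and 78.9% remained. Regrouping the 10 libraries of a comparison gave as many calls in only 1 of 100 splits each time, the real grouping itself. In fits of only the 2 groups compared, the real grouping had 3442 calls in 82Q against WT (highest other 0). It had 5893 in 82Q_M120A against WT (highest other 1) and 2438 in 82Q_M120A against 82Q (highest other 1). The main fit called 3142, 6118 and 3175. Every other split mixed both groups on each side, so their differences entered the spread and held calls down. The other splits therefore give no chance level for the calls.

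Genes of microglia and reactive glia rose in 82Q while Purkinje cell genes fell, and a smaller share of Purkinje cell RNA could raise the share of every other cell type. That would lift granule cell genes as well, but the microglia median lay above the granule cell median by 0.78 log2 units, more than the summed interquartile half-widths of 0.21. Choroid plexus tissue and sex do not account for the rise, since 96.6% of these glial calls remained with the choroid plexus score as a covariate and 89.7% with the Xist level. Other tissue was not tested as a covariate. In 82Q against WT the list medians were 0.07 for meninges and fibroblasts, 0.01 for brainstem and cerebellar nuclei and 0.11 for vascular genes. The microglia median was 0.74. Whether more microglia or more RNA per cell lie behind the rise stays open in bulk RNA.

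Choroid plexus genes differ strongly between libraries of one group. Their levels go together across the 15 libraries, with a median correlation of 0.97 between members (0.74 to 1), in line with choroid plexus tissue carried along in some dissections. The Xist level explains 0.2% of the variance of this score within groups, which argues against sex as its source. The tissue that was taken is not described further in the sources used here.

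Single libraries stood apart from the other 4 of their group by Dixon's ratio (gap over range, above 0.71) in 9 of 84 group and list pairs and in 21 of 267 group and gene pairs, where chance flags about 1 in 20 groups, that is 4.2 and 13.3. WT-5, at 38.3 M counts the shallowest library (ratio 0.801), stood apart 9 times. It was the WT library without Xist (0.802 CPM against 1140 in each other, ratio 0.999) and with Ddx3y (104 CPM against 0 to 0.167, 0.756), so its sex-linked score was high (0.784). WT-5 also had the lowest Itgax (0.917), Galr1 (0.775) and Trhr (0.757) and the highest Shank2 (0.818) and oxidative phosphorylation score (0.744) in WT. In 82Q-5 the scores of Purkinje cell genes (6.65 against 6.8 to 6.85, ratio 0.716) and of mGluR1 and calcium signalling genes (7.38 against 7.51 to 7.55, 0.807) were the lowest of 82Q, with Itpr1 (0.727). 82Q_M120A-3 was the lowest of its group for Gng13 (26.5 CPM against 37.9 to 40.3, ratio 0.855), Cck (0.731), Slco1a4 (0.74), Rpl29 (0.733) and Hspe1 (0.849). The choroid plexus score was low in WT-4 (0.68 against 4.65 to 5.35, ratio 0.85) and high in 82Q_M120A-1 (4.94 against 0.36 to 0.83, 0.898), and Ttr followed (0.904 and 0.833). WT-4 was also the lowest of WT for Etv4 (0.742) and Slco1a4 (0.743). The granule cell score was lowest in 82Q_M120A-1 (8.56 against 8.69 to 8.7, ratio 0.947). Vascular scores stood apart in 82Q-3 (4.3 against 4.39 to 4.41, ratio 0.815) and 82Q_M120A-5 (4.59 against 4.49 to 4.5, 0.834), and 82Q_M120A-5 had the lowest Dynlt1b (0.746) of its group. Hspa5 in 82Q-4 (0.717), A630020A06 in 82Q_M120A-4 (0.73 CPM against 0.174 to 0.204, ratio 0.893), Npas4 in 82Q_M120A-2 (0.792) and Alad in WT-1 (0.823) complete these values, and no library was left out of the tests.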

How the results depend on the processing

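The alternatives written before the data were examined and the covariates added later left most results in place. Of 318 pairs of named gene and comparison, DESeq2 and RLE factors weakened 0, limma-voom 10, library size only 7, no low-count filter 9, a fit of only the groups compared 19, the choroid plexus covariate 16, the Xist covariate 12 and both together 19. Adjusted p under 0.01 weakened 61 and the test against a 1.2-fold change 140, because both ask for more. Leaving out 1 library took the call from 33 pairs at least once. Of the 318 pairs 314 were called in the main fit, most of them named for a large change or a small adjusted p. This choice favours keeping the call, so the tally does not measure how stable the other calls are. Sign changes were confined to genes that were not called: Prkaca in 82Q against WT with library size only (0.019), and Atxn1 in 82Q_M120A against WT with the choroid plexus covariate (-0.034) or both covariates (-0.03) and over the libraries left out (-0.018 without WT-5 to 0.087 without WT-4); the cause was not tested. At adjusted p under 0.01 the calls were 1823 for 82Q against WT, 4060 for 82Q_M120A against WT and 1645 for 82Q_M120A against 82Q, with 150 genes moved back and 1402 called against WT in both, and at 1.2-fold 689, 1709 and 630. Of the 25 called lists 11 lost the call with an estimated correlation, which left 7 lists in 82Q_M120A against WT and 0 against 82Q. The lists called in 82Q_M120A against 82Q numbered 5 without the low-count filter, with the choroid plexus covariate and with both covariates, and 2 to 6 with 1 library left out. The slope was 0.866 without the low-count filter and 0.927 to 0.951 in the other fits of all libraries. No paired analysis was possible because the columns carry no replicate number that ties libraries of different groups together.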

Other observations

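Groups of genes that mark time of day, activity or stress were not called by camera, though single members changed. In 82Q_M120A against 82Q the clock gene Per2 fell by 0.52 log2 units (adjusted p = 0.00427) and Bhlhe41 rose by 0.27 (adjusted p = 0.0039), with 2 of 15 circadian genes higher and 2 lower (camera adjusted p = 0.68) and no circadian gene called in 82Q against WT (0.677). Among immediate early genes Npas4 fell by 1.22 (adjusted p = 0.0125) and Btg2 rose by 0.32, with 1 of 12 genes higher and 3 lower (camera adjusted p = 0.582), and 2 were higher in 82Q against WT, Btg2 and Arc (0.536). Against WT more members were called in 82Q_M120A: 3 of 12 immediate early genes rose and 3 fell (0.989), 3 of 18 genes of the unfolded protein response rose and 4 fell (0.85), and 3 of 15 circadian genes rose and 1 fell (0.989). The endoplasmic reticulum chaperone genes Hspa5 and Manf fell by 0.29 and 0.30 in 82Q_M120A against 82Q, where 3 of 18 genes of the unfolded protein response fell (3 higher and 8 lower when adjusted over the list alone, camera adjusted p = 0.529). In 82Q against WT only Atf3 of that list rose (0.76 ± 0.11, adjusted p = 8.22e-05; list 0.683). No cytosolic heat shock gene was called in 82Q against WT (camera adjusted p = 0.72), and 5 of 15 fell and 1 rose in 82Q_M120A against WT (0.296, and 0.0412 by fry), with Hspe1 lower by a log2 fold change of -0.21.

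Camera called no list of marker genes of neighbouring tissue. None of the 12 genes of meninges and fibroblasts was called in 82Q against WT (camera adjusted p = 0.516). Of 9 genes of brainstem and cerebellar nuclei 1 rose and 1 fell (0.72), the tyrosine hydroxylase gene Th from 4.47 ± 0.993 to 1.43 ± 0.325 CPM (log2 fold change -1.65 ± 0.18, adjusted p = 1.78e-06), and Th was as low in 82Q_M120A (1.43 ± 0.254). In 82Q_M120A against WT 2 genes of that list rose and 3 fell (0.568, but 0.038 by fry). All 14 choroid plexus genes had lower means than in WT, with log2 fold changes of -1.37 to -0.19 in 82Q (median -0.61, none called, 0.536) and of -2.24 to -0.5 in 82Q_M120A (median -1.93, 1 called, 0.0962). The score of this list was 4.15 ± 1.95 in WT, 3.08 ± 1.99 in 82Q and 1.49 ± 1.94 in 82Q_M120A (exact permutation tests against WT, two-sided, p = 0.484 and 0.0873), and Ttr stood at 1650 ± 973 CPM in WT, 979 ± 1200 in 82Q and 395 ± 853 in 82Q_M120A. None of the 6 sex-linked genes was called in 82Q against WT (camera adjusted p = 0.68). Xist, at 914 ± 510, 532 ± 727 and 905 ± 825 CPM, and Ddx3y, at 20.8, 69 and 40.4 CPM, varied within every group. Ddx3y was at 97.1 to 128 CPM, with Xist at most 2.56, in WT-5, 82Q-2, 82Q-3, 82Q-4, 82Q_M120A-2 and 82Q_M120A-4. In all other libraries Ddx3y was at most 0.167 CPM. The mix of the sexes therefore differed between groups, and the lack of calls does not show balance. In the strain-variable list 2 of 13 genes fell in 82Q against WT (0.677), the class I histocompatibility gene H2-D1 from 113 ± 3.87 to 62.1 ± 5.26 CPM and Alad, which encodes a heme synthesis enzyme, from 112 ± 3.37 to 82.6 ± 1.83, although both groups carry the same strain label. In 82Q_M120A these genes stood at 50.2 ± 12.6 and 58.5 ± 13.4 CPM, and 4 strain-variable genes rose and 4 fell against 82Q (camera adjusted p = 0.6) and 3 rose and 4 fell against WT (0.471, but 0.0224 by fry).

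Some genes were chosen after their values were seen. Colec10 (chr15:54410774-54466358), a collectin gene, had 2 counts over the 5 WT libraries, 638 in 82Q and 492 in 82Q_M120A, a ratio of 264 for 82Q against WT with a counting interval of 72.7 to 2180 that covers counting error only. Its neighbours on chromosome 15 differed less, Tnfrsf11b by a log2 fold change of 0.67 (adjusted p = 0.0158), Samd12 by 0.20 (0.0239) and Mal2 by 0.02 (0.905, not called). Genes of activated microglia chosen in the same way rose in 82Q against WT, the elastase gene Mmp12 by 4.19 (adjusted p = 2.86e-07), the chemokine genes Ccl3 by 2.53 (1.42e-05) and Ccl4 by 2.69 (6.05e-05), and the lectin gene Cd22 by 2.61 (1.21e-05), all by edgeR quasi-likelihood. H2-T23 and Bub1b rose in 82Q_M120A against 82Q by 2.49 ± 0.59 and 3.95 ± 0.87 with libraries from 1.18 to 11.5 and from 0.62 to 13.5 CPM, and limma-voom did not call them (adjusted p = 0.128 and 0.119); reads of H2-T23 can be shared with other genes of its family.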
